A study of Mus musculus with 4 samples.

How the data were processed

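Total RNA of cultured mouse cortical neurons was extracted with TRIzol and depleted of ribosomal RNA with a kit from NEB, per the labels' protocols, and 4 libraries were sequenced, 2 from neurons given DMSO and 2 from neurons given the p53 activator Nutlin-3. The treatment label of the DMSO samples reads as untreated while their titles name DMSO, and the titles were followed. The submitters' processing notes name TopHat2 without a version, Cufflinks 2.0.0 and the genome build mm9, with no role for any of them. The program that counted reads, its use of strand, the annotation and any filter on rows are not given in the sources used here, and some symbols in the table are newer than that build.

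The authors deposited 1 table with a column of CPM per library for 18854 genes, each under its own symbol. No file header or label names the unit. It was read from the values: within a column every value is a whole multiple of 1 step, and columns sum to just under the total that CPM implies. The steps gave back whole reads for 100% of values, within 0.01 reads. The totals behind the columns were 14584247 and 14968028 reads for DMSO and 19065197 and 17716272 for the p53 activator, of which 0.208%, 0.191%, 0.149% and 0.133% fell outside the listed genes. At these depths 1 read is worth 0.0686, 0.0668, 0.0525 and 0.0564 CPM.

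The plan was fixed before the data were examined and had assumed FPKM, on account of Cufflinks. The same test was used on CPM, with the same limits. Genes with at least 1 CPM in at least 2 libraries were kept, which left 16654 and removed 2200. Values were taken as log2(CPM + 1), so fold changes of low genes are understated. limma 3.58.1 in R 4.3.3 fitted the group difference, with empirical Bayes moderation and a trend of the spread with expression, and Benjamini-Hochberg adjustment, two-sided, with calls at an adjusted p under 0.05. With 4 libraries there were 2 residual degrees of freedom, and the moderation added 98.0 prior degrees of freedom, so the calls lean on a spread shared across genes. The median SE of a log2 fold change was 0.13. A group of 2 is too small for tests of outlying samples or of other splits of the samples. Intervals on log2 fold changes are limma's, at 95%.

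The genes named in the text followed a rule set beforehand. It took Trp53, Mdm2 and Cdkn1a in any case, the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 2 CPM (leaving out predicted genes and small RNA symbols), the 6 called p53 targets with the smallest p, the 2 called members with the smallest p of each other list, and the most abundant member of each marker list with no call. Some genes that the rule takes are not reported here. Genes named in addition were chosen after their values were seen.

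Gene lists of pathways and of cell type markers were also written beforehand. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 31 lists tested, and again with an estimated correlation. No gene in the table had a symbol starting with Hist, and 2 had one starting with mt-, of which mt-Rnr1 fell. So 2 lists, of mitochondrially encoded proteins and of histones under the symbols in use, were added after the data were seen. Of the lists, 14 were called, 13 of them higher. With an estimated correlation 0 were called (smallest adjusted p = 0.593). At the preset correlation, 5 of the 14 were called among protein-coding genes and 3 after cyclic loess, where 1 and 2 other lists were called lower. Each list's median was also set against 10000 random lists of protein-coding genes matched on mean expression in 40 bins, and 0 lists were called at an adjusted p under 0.05 (smallest adjusted p = 0.0638, for excitatory synapse genes and ribosomal proteins, both lower than matched lists).

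Gene classes and the place of lncRNAs relative to protein-coding genes came from GENCODE vM21, in which 15860 of the 18854 symbols matched 1 gene. Its build differs from the one the notes name, so no coordinates are given.

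The alternatives planned were other pseudocounts (0.1 and 0.5), no filter and a minimum of 5 CPM, quantile normalization, size factors, other variance models, array weights, a replicate block, a fold limit and leaving out each library. Those added after the data were seen were edgeR 4.0.16 quasi-likelihood tests and DESeq2 1.42.0 on the recovered whole reads, and fits on protein-coding genes scaled to their own total or aligned by cyclic loess. edgeR with TMM called 1872 genes higher and 2846 lower among 17710.

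The limma step was tested on simulated data, in 10 runs that drew counts for the real genes from the real means, library totals and edgeR dispersions and changed 200 genes. For this comparison, with a median of 16568 genes tested, it recovered 20.6% of genes changed 1.25-fold, 58.4% at 1.5-fold, 84.2% at 2-fold and 95.4% at 3-fold, and 3.36% of calls were false. The camera step called a list raised 1.25-fold in 10 of 10 runs and called 0 unchanged lists. Simulated genes varied independently, which real genes do not. Apart from the 200 changed genes both groups were drawn from the same means, so the runs held no shift in composition between groups. The share of false calls therefore holds for the simulated data only.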

Results

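RNA sequencing measured gene expression in cultured mouse cortical neurons that had been kept in culture for 15 days and then exposed for 2 days to Nutlin-3, or that received the solvent DMSO. Nutlin-3 is a small molecule that blocks the binding of Mdm2 to p53, which otherwise marks p53 for degradation, and it is used to activate p53. There were 2 libraries per group. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The values were CPM, read counts scaled to 1 common total per library, for 18854 genes, resting on 14584247 and 14968028 counted reads in the DMSO libraries and 19065197 and 17716272 in the p53 activator libraries. Within each group the replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.64 for DMSO and 5.34 for the p53 activator.

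The libraries differed in composition by group. Mitochondrially encoded RNAs took 15.6% and 14.3% of the reads in the DMSO libraries and 8.95% and 9.98% in the p53 activator libraries. Nuclear protein-coding genes took 73.4% and 75.8% of the reads in DMSO and 83.1% and 82.6% with the activator. CPM values share a fixed total per library, so each rise of a protein-coding gene stands beside this shift in composition.

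**Figure D1:**
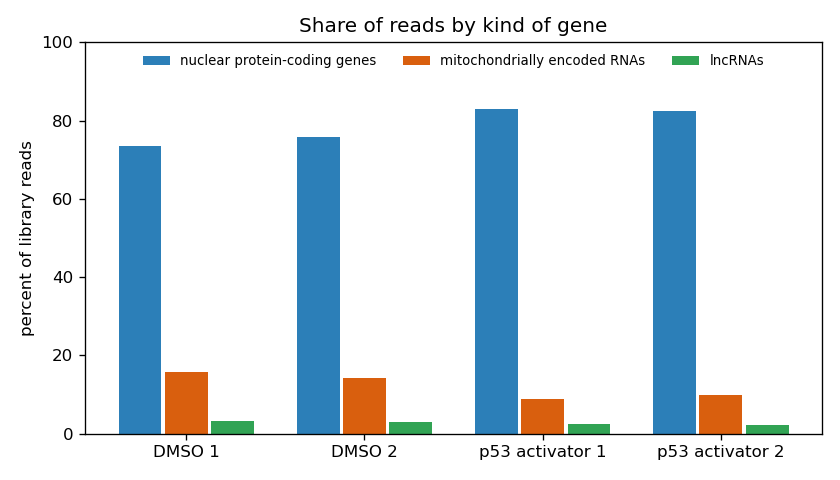
Percent of library reads (vertical axis) held by nuclear protein-coding genes, mitochondrially encoded RNAs and long noncoding RNAs in each of the 4 libraries, 1 bar per library and kind of gene. The mitochondrial share was 15.6% and 14.3% in DMSO and 8.95% and 9.98% with the p53 activator.

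The comparison of the p53 activator with DMSO asks how neurons change their gene expression once p53 is released from Mdm2. Small rises of many abundant mRNAs were set against larger falls of noncoding and mitochondrial RNAs, while Trp53, Mdm2 and Cdkn1a did not pass the test. Of 16654 genes tested, 2811 rose and 2721 fell. The rises were small: 18 genes rose by at least 1.5-fold and 3 by at least 2-fold, against 1627 and 262 that fell by as much. The 3 were Gm15564, Mir6236 and Gm53756, which were singled out after their values were seen. Gm15564 stood at 2.19 and 2.54 CPM in DMSO and at 6.19 and 14.8 CPM with the activator. Mir6236 stood at 2.13 and 1.54 CPM in DMSO and at 4.09 and 8.07 CPM with the activator. Without p53 activator replicate 2 the log2 fold changes of Gm15564 and Mir6236 were 1.10 and 0.85. Of the 262 genes that fell by at least 2-fold, 9 were protein coding, and the other 253 were noncoding or had no match in the annotation. The median absolute log2 fold change of the called genes was 0.40, and the groups did not overlap for 67.6% of the genes tested, where chance gives 33.3%.

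Among named protein-coding genes, the largest rises were of low abundance. C1qtnf1, which encodes a secreted protein of the C1q and TNF family, rose from 1.83 ± 0.158 to 3.55 ± 0.569 CPM (SD, n = 2 each), with a log2 fold change of 0.68 ± 0.20 (SE) and a limma adjusted p of 0.00454. Wdr89 (log2 fold change 0.67), Shisa2 (0.66), Nr2c2ap (0.64), Ccdc184 (0.62), Dach1 (0.62), Arl4d (0.60) and Chst8 (0.60) followed. Dach1 is a transcriptional repressor and Chst8 a carbohydrate sulfotransferase. The calls of C1qtnf1, Wdr89, Shisa2, Nr2c2ap and Dach1 were lost without DMSO replicate 1, those of Wdr89, Dach1 and Arl4d without p53 activator replicate 1, and those of C1qtnf1 and Nr2c2ap without p53 activator replicate 2.

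The largest fall was that of Bc1, a short noncoding RNA of dendrites that represses translation. It stood at 319 and 123 CPM in the DMSO libraries and at 10.2 and 40.1 CPM in the p53 activator libraries, a log2 fold change of -3.21 ± 0.18 (SE). Its spread within groups was wide, and limma's robust variance model ended its call (adjusted p = 0.212). Mitochondrial ATP8, which overlaps ATP6 on the mitochondrial genome so that the reads of the pair are hard to separate, fell with a log2 fold change of -1.63, and that call also ended under the robust model (adjusted p = 0.0799). The mitochondrial transfer RNAs TrnE (-1.26) and TrnS1 (-1.25) fell too. Nup50l (-1.28) and Semp2l1 (-1.27) fell as well, but each is named as a relative of another gene, with which the authors' counting may have shared reads. P2ry13, a purine receptor, fell from 2.64 ± 0.239 to 0.577 ± 0.222 CPM (log2 fold change -1.21). Kcnip4, a partner of voltage-gated potassium channels, was abundant and fell from 1678 ± 73.6 to 727 ± 87.6 CPM (SD, n = 2 each), a log2 fold change of -1.21 ± 0.10 (SE) with a limma adjusted p of 1.37e-19.

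These counts depended on the scaling and on how the spread was estimated. Rises made up 50.8% of the calls here and 39.7% with edgeR's TMM scaling of the recovered reads. Among nuclear protein-coding genes alone, 2708 rose and 917 fell here. When these were scaled to their own total, 554 rose and 1665 fell (24.97% of calls rises). When they were aligned by cyclic loess, 636 rose and 1243 fell (33.8%). Of all genes tested, 302 rose when limma's spread did not follow expression. Without DMSO replicate 1 the counts were 1138 higher and 1445 lower, without p53 activator replicate 1 1662 genes rose, and without p53 activator replicate 2 1779 genes fell. Without DMSO replicate 1, DMSO replicate 2, p53 activator replicate 1 or p53 activator replicate 2, 37, 98, 45 and 54 genes rose by at least 1.5-fold, and 178, 436, 509 and 177 fell by at least 2-fold. Quantile normalization gave 174 rises and 976 falls of at least 1.5-fold, and the genes lower by at least 2-fold were 835 at a pseudocount of 0.1 and 1044 in edgeR with TMM.

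Trp53 and the p53 targets Mdm2 and Cdkn1a did not pass the test. Nutlin-3 acts by keeping p53 protein from degradation, so the level of Trp53 mRNA does not check the drug. Trp53, which encodes p53, stood at 7.65 ± 0.811 CPM in DMSO and 8.09 ± 0.766 CPM with the activator (SD, n = 2 each), a log2 fold change of 0.07 ± 0.16 (SE) with a limma adjusted p of 0.761. Mdm2, the ubiquitin ligase that Nutlin-3 binds and itself a p53 target, stood at 47.7 ± 0.636 and 42.6 ± 3.60 CPM (-0.16 ± 0.09, adjusted p = 0.166). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 18.2 ± 0.143 and 20.9 ± 2.57 CPM (0.19 ± 0.12, adjusted p = 0.215). The upper 95% limits of the log2 fold change were 0.39 for Trp53, 0.02 for Mdm2 and 0.42 for Cdkn1a. Without DMSO replicate 1, DMSO replicate 2, p53 activator replicate 1 or p53 activator replicate 2, the log2 fold change was 0.17, -0.02, 0.16 and -0.01 for Trp53, -0.15, -0.17, -0.25 and -0.08 for Mdm2 and 0.20, 0.18, 0.07 and 0.31 for Cdkn1a, none of them called. With protein-coding genes scaled to their own total, Trp53 had a negative log2 fold change of -0.06 (adjusted p = 0.840) and Mdm2 fell (-0.31, adjusted p = 0.00960).

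Of the 47 tested p53 targets, 10 rose and 0 fell, and 8 rose when adjusted over the list alone. That is 21.3% of the targets, beside 21.2% of nuclear protein-coding genes. Plk2, a kinase that scales synapses, rose from 112 ± 5.41 to 141 ± 4.67 CPM (SD, n = 2 each; log2 fold change 0.32 ± 0.08 SE, limma adjusted p = 0.000609). Zmat3, an RNA-binding protein, rose from 139 ± 3.77 to 172 ± 4.95 CPM, and Ccng1, which encodes cyclin G1, from 81.3 ± 4.51 to 102 ± 5.68 CPM. Tigar, a fructose bisphosphatase that slows glycolysis, the thiamine transporter Slc19a2 and the adenylate kinase Ak1 rose by 0.37, 0.38 and 0.29 on the log2 scale. The list's median log2 fold change was 0.12, and its highest member stood at 0.41. The upper 95% limit lay below what a 1.5-fold rise of the target's own DMSO level would show on the log2(CPM + 1) scale for 33 of the 47 targets, and below what a 2-fold rise would show for 46 of 47, all but Perp. The camera test called the list higher than other genes (adjusted p = 0.0480), with an adjusted p = 0.796 with an estimated correlation and an adjusted p = 0.244 among protein-coding genes. When protein-coding genes were scaled to their own total, 0 targets rose and 1 fell, which was Mdm2, and 0 also rose when limma's spread did not follow expression. Without DMSO replicate 1, and again without p53 activator replicate 1, 3 targets rose, and the camera call was lost without DMSO replicate 1 (adjusted p = 0.0833), DMSO replicate 2 (0.0521) or p53 activator replicate 1 (0.145).

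**Figure D2:**
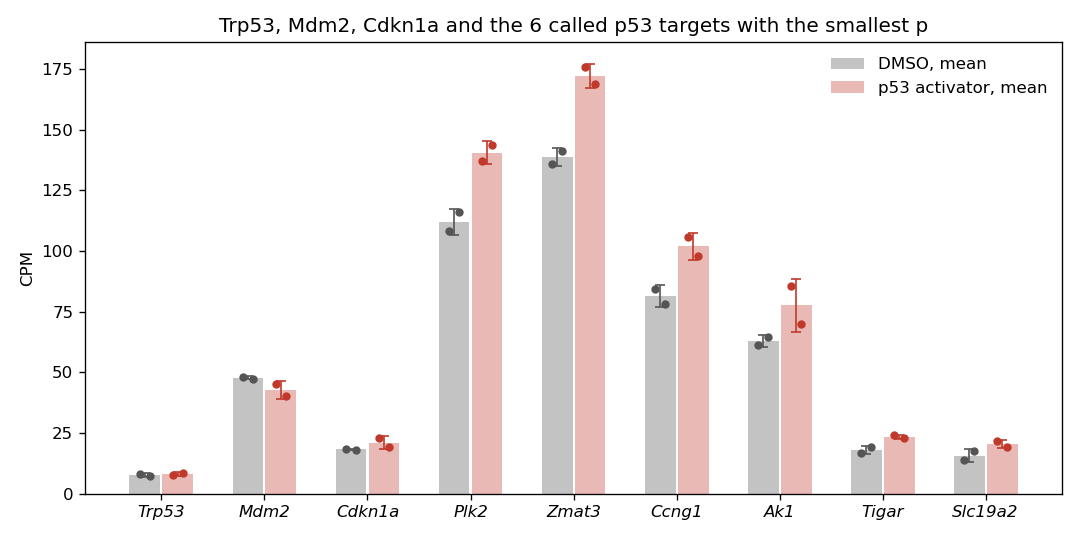
CPM (vertical axis, from 0) of Trp53, Mdm2, Cdkn1a and the 6 called p53 targets with the smallest p in DMSO (grey) and p53 activator libraries (red). Bars are means, error bars the SD and dots the 2 libraries of each group, and Zmat3 shows the highest level, 139 CPM in DMSO and 172 CPM with the activator.

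The lists of p53 regulators, apoptosis, cell cycle and DNA repair genes were not called by camera. Of 23 tested p53 regulators, 4 rose and 2 fell (camera adjusted p = 0.590). Ppm1d, a phosphatase that turns p53 off and also a listed target, rose (log2 fold change 0.36), and the DNA damage kinase Atr fell (-0.32). Among 21 genes that promote apoptosis 3 rose and 0 fell (adjusted p = 0.249), with the BH3-only gene Hrk higher by 0.23 on the log2 scale. Of 9 genes that restrain apoptosis, Bcl2l2 (0.25) and Bcl2l1 (0.22) rose (adjusted p = 0.354). Cdk4 was the only one of 44 cell cycle genes called (0.24, list adjusted p = 0.954). Of 32 DNA repair genes 2 rose and 2 fell (adjusted p = 0.905), among them the end-joining ligase Lig4, which rose by 0.53, and the repair polymerase Polb, which fell (-0.44). Of 12 senescence and secreted factors 5 rose and 2 fell (adjusted p = 0.328), with the cell cycle inhibitor Cdkn1b up from 35.3 ± 2.85 to 46.1 ± 0.494 CPM and the protease inhibitor Timp1 down from 2.47 ± 0.290 to 0.788 ± 0.00245 CPM. Of 10 interferon and innate response genes H2-D1 rose (0.51, list adjusted p = 0.892), while 11 of the 26 genes on that list were not listed in the table. In edgeR with TMM the calls of Hrk (adjusted p = 0.0686), Bcl2l2 (0.0655), Bcl2l1 (0.0960) and Cdk4 (0.0860) were lost, and the rises and falls were 2 and 2 for p53 regulators, 1 and 1 for genes that promote apoptosis, 0 and 0 for those that restrain it and 0 and 2 for the cell cycle. Adjusted over the list alone, the rises and falls were 3 and 2 for p53 regulators, 1 and 0 for each apoptosis list, 0 and 0 for the cell cycle, 2 and 1 for DNA repair, 5 and 2 for senescence and 1 and 0 for interferon. Leaving out DMSO replicate 1, 0 p53 regulators, 0 genes that promote apoptosis and 1 senescence gene rose. Without p53 activator replicate 1, 0 regulators and 1 apoptosis-promoting gene rose, and without p53 activator replicate 2, 0 regulators and 2 senescence genes rose.

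Lists of presynaptic, inhibitory synapse and neurite growth genes were called higher at the preset correlation and not with an estimated one (adjusted p = 0.593 for each). Of 22 presynaptic vesicle genes 15 rose and 0 fell (median log2 fold change 0.30, camera adjusted p = 7.41e-07; 18 and 0 adjusted over the list alone). The vesicle glycoprotein Sv2a rose 1.44-fold, from 245 and 296 CPM to 366 and 410 CPM in the 2 libraries of each group, and the vesicle GTPase Rab3a 1.34-fold, from 123 ± 0.566 to 165 ± 1.59 CPM (SD, n = 2 each). Of 20 inhibitory synapse genes 14 rose and 0 fell (median 0.29, adjusted p = 2.10e-06; 16 and 0 adjusted over the list alone). Slc32a1, the vesicular GABA transporter, rose 1.49-fold, from 60.5 ± 5.49 to 90.7 ± 2.67 CPM. Of 20 genes of neurite growth and axon injury 9 rose and 0 fell (median 0.21, adjusted p = 0.000597; 9 and 0 adjusted over the list alone). The neuronal tubulin Tubb3 rose from 365 ± 19.3 to 535 ± 23.2 CPM and the microtubule regulator Stmn2 from 723 ± 25.5 to 1015 ± 10.9 CPM. At the preset correlation the 3 lists stayed called among protein-coding genes (adjusted p = 1.31e-05, 4.04e-05 and 0.00617), where 9, 7 and 4 members rose and 1, 1 and 0 fell. After cyclic loess the presynaptic and inhibitory lists were called (adjusted p = 0.0393 each) and the neurite growth list was not (0.236), and the medians of the 3 lists, 0.30, 0.29 and 0.21, stood beside 0.22, 0.21 and 0.20 for protein-coding lists matched on expression (adjusted p = 0.142, 0.193 and 0.909, from 10000 matched lists).

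Excitatory synapse genes went both ways. Of 25 tested, 9 rose and 2 fell (median 0.09, camera adjusted p = 0.172; 9 and 3 adjusted over the list alone). The NMDA receptor subunits Grin1 and Grin2a rose by 0.47 and 0.37 on the log2 scale, while the scaffold Shank1 and the exchange factor Kalrn were the 2 that fell, and were named for that. When protein-coding genes were scaled to their own total, 3 members rose and 8 fell, and after cyclic loess the list was called lower (adjusted p = 0.0305). The list's median of 0.09 lay below the 0.22 of protein-coding lists matched on expression (adjusted p = 0.0638 against those lists). Of 27 ion channel genes of excitability 13 rose and 2 fell (median 0.18, adjusted p = 0.00763; 14 and 2 adjusted over the list alone). The ion channel list had an adjusted p = 0.796 with an estimated correlation, and was not called among protein-coding genes (adjusted p = 0.434). Its median of 0.18 did not exceed the 0.20 of protein-coding lists matched on expression (adjusted p = 0.757 against those lists). The potassium channel Kcna1 rose from 161 ± 10.96 to 222 ± 5.09 CPM, and Kcnd2, the channel that Kcnip4 binds, fell from 290 ± 1.22 to 213 ± 2.61 CPM. Of 24 activity-regulated genes 7 rose and 1 fell (median 0.19, adjusted p = 0.0480; 8 and 1 adjusted over the list alone). The activity list had an adjusted p = 0.726 with an estimated correlation, and an adjusted p = 0.244 among protein-coding genes. Its median of 0.19 lay above the 0.09 of lists matched on expression, with an adjusted p = 0.138 against those lists. Nr4a3 rose from 56.1 ± 4.62 to 77.5 ± 2.75 CPM, and Npas4, a transcription factor induced by calcium entry, fell from 25.2 ± 1.07 to 16.7 ± 2.25 CPM.

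These neuronal counts shrank in edgeR and when 1 library was left out. In edgeR with TMM, 5 neurite growth, 4 excitatory synapse, 8 ion channel and 3 activity-regulated genes rose. When DMSO replicate 1 was left out, 9 inhibitory synapse, 3 neurite growth, 3 excitatory synapse, 4 ion channel and 2 activity-regulated genes rose. Without p53 activator replicate 1, 9 inhibitory synapse, 4 neurite growth, 5 excitatory synapse and 6 ion channel genes rose. Without p53 activator replicate 2, 5 neurite growth, 3 excitatory synapse, 8 ion channel and 2 activity-regulated genes rose, and without DMSO replicate 2, 4 activity-regulated genes rose. The camera call of the ion channels was lost without DMSO replicate 1 (adjusted p = 0.0757) or p53 activator replicate 2 (0.0657), and that of the activity-regulated genes without DMSO replicate 2 (0.0903) or p53 activator replicate 2 (0.374). The excitatory synapse list was called higher without DMSO replicate 2 (0.0366).

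**Figure D3:**
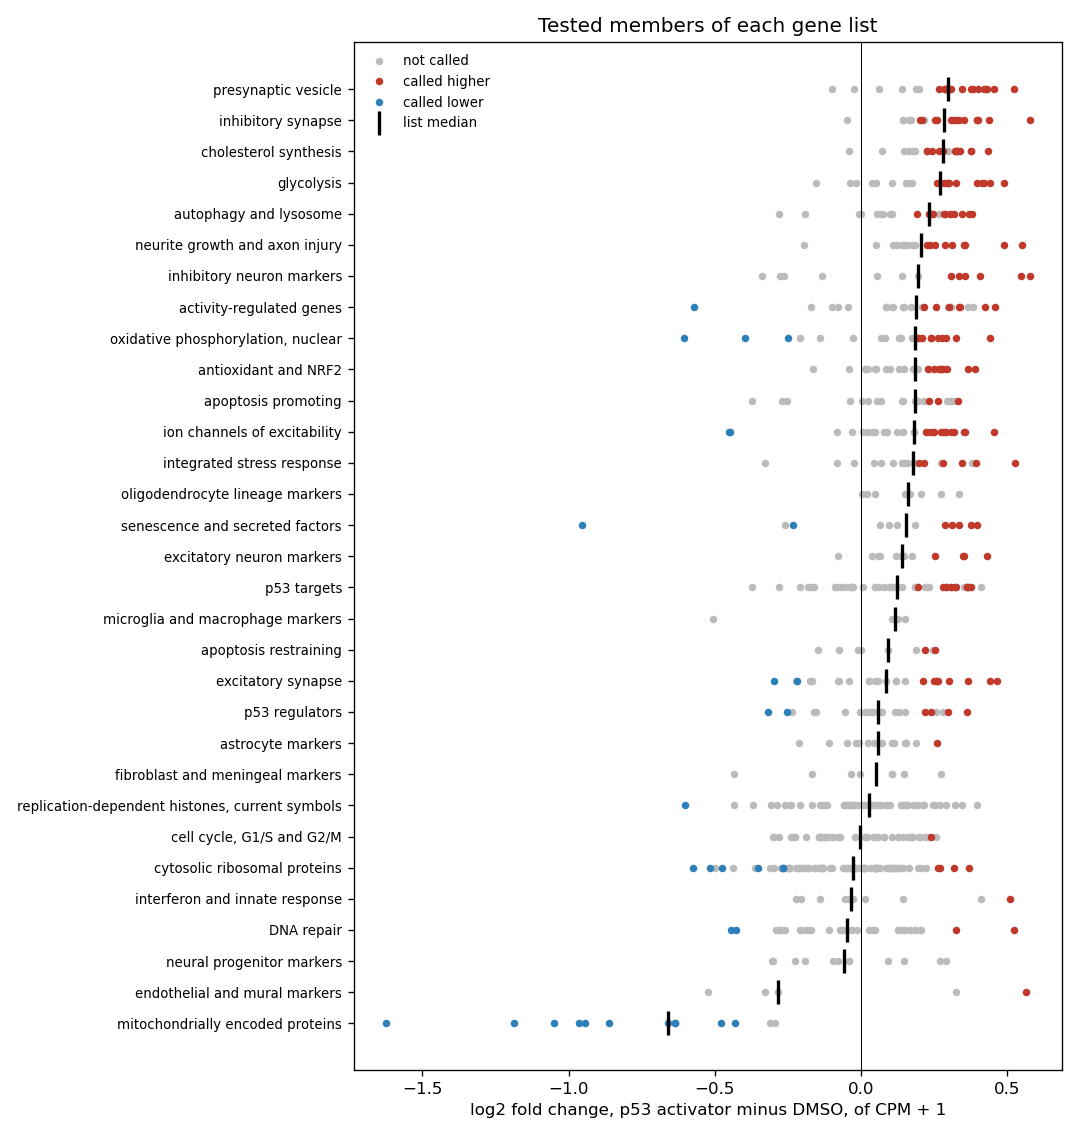
Log2 fold change of CPM + 1, p53 activator minus DMSO (horizontal axis), of the tested members of each gene list (rows, sorted by median). Dots are genes, red called higher, blue called lower and grey not called, and black marks are list medians, from 0.30 for presynaptic vesicle genes to -0.66 for mitochondrially encoded proteins.

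Lists of cholesterol and glycolysis genes were likewise called higher at the preset correlation, with an adjusted p = 0.593 for both with an estimated correlation. Of 21 genes of cholesterol synthesis and uptake 14 rose and 0 fell (median 0.28, camera adjusted p = 9.57e-06; 18 and 0 adjusted over the list alone). Sqle, which oxidises squalene, rose 1.30-fold, from 292 ± 22.0 to 380 ± 10.2 CPM (SD, n = 2 each). Of 20 glycolysis genes 11 rose and 0 fell (median 0.27, adjusted p = 0.000433; 11 and 0 adjusted over the list alone), among them Pgam1, from 65.6 ± 6.50 to 92.3 ± 2.17 CPM, and Tpi1, from 127 ± 8.43 to 173 ± 11.4 CPM. At the preset correlation both lists stayed called among protein-coding genes (adjusted p = 0.000381 and 0.00956), where 3 and 5 members rose and 0 and 1 fell. After cyclic loess the cholesterol list was called (adjusted p = 0.0393) and the glycolysis list was not (0.106), and their medians stood beside 0.18 and 0.16 for lists matched on expression (adjusted p = 0.0986 and 0.0851, from 10000 matched lists). With DMSO replicate 1 left out, 6 cholesterol genes rose, and without p53 activator replicate 1, 9 did, as many as in edgeR with TMM.

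Of 23 genes of autophagy and the lysosome 12 rose and 0 fell (adjusted p = 0.00295, and adjusted p = 0.593 with an estimated correlation), including Gabarapl1 (0.38) and Atg12 (0.37), which act in making autophagosomes. Of 25 antioxidant genes 9 rose and 0 fell (adjusted p = 0.00763, and adjusted p = 0.593 with an estimated correlation), including the mitochondrial peroxidase Prdx3 (0.39) and the cystine transporter Slc7a11 (0.28). Of 19 genes of the integrated stress response 6 rose and 0 fell (adjusted p = 0.0216, and adjusted p = 0.593 with an estimated correlation), including the amino acid transporter Slc7a5 (0.40) and the mTORC1 inhibitor Ddit4 (0.53). Adjusted over the list alone, 14, 9 and 8 of these rose and 0 fell. Among protein-coding genes these 3 lists had an adjusted p = 0.0615, 0.134 and 0.146, with 3, 1 and 2 members higher. Their medians, 0.23, 0.19 and 0.18, stood beside 0.14, 0.12 and 0.11 for protein-coding lists matched on expression (adjusted p = 0.138, 0.288 and 0.288 against those lists). Of these lists, 5, 4 and 3 members rose without DMSO replicate 1, and 7, 6 and 3 in edgeR with TMM. Without DMSO replicate 2, 5 antioxidant genes rose, and without p53 activator replicate 1, 2 did. Without p53 activator replicate 2, 3 stress response genes rose and the camera call of that list was lost (adjusted p = 0.0657).

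Nuclear genes of oxidative phosphorylation went both ways, with 10 of 25 higher and 3 lower (camera adjusted p = 0.0598; 13 and 3 adjusted over the list alone). The complex III gene Uqcrfs1 rose from 47.5 ± 0.0584 to 65.0 ± 6.82 CPM, and the complex IV gene Cox6c fell from 56.0 ± 10.5 to 36.3 ± 4.03 CPM. Without DMSO replicate 1, 2 rose, 1 fell and the list was called higher (adjusted p = 0.0342). Without DMSO replicate 2, 5 rose, without p53 activator replicate 1, 3 rose, and without p53 activator replicate 2 the list was called higher (0.0289). With protein-coding genes scaled to their own total, 1 rose and 4 fell, and in edgeR with TMM 3 rose and 3 fell. Of 86 genes of cytosolic ribosomal proteins, many of which have near-identical pseudogene copies, 4 rose and 6 fell (adjusted p = 0.634; 3 and 2 adjusted over the list alone), with Rpl15 at 48.2 ± 2.47 and 62.9 ± 9.04 CPM and Rps21 at 12.1 ± 2.52 and 7.76 ± 1.40 CPM. Among protein-coding genes scaled to their own total, 0 rose, 15 fell and that list was called lower (adjusted p = 0.0103). Without DMSO replicate 1, 2 rose and 0 fell. Without DMSO replicate 2, 1 rose, and without p53 activator replicate 1, 0 rose and 3 fell. Of 58 replication-dependent histone genes, gathered after the data were seen under the symbols in use in the table, 0 rose and H3c13 fell (-0.60, list adjusted p = 0.892). Under quantile normalization 5 rose and 0 fell.

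Of 13 mitochondrially encoded protein genes, a list added after the data were seen, 11 fell and 0 rose (median log2 fold change -0.66, camera adjusted p = 2.60e-11, and an adjusted p = 0.593 with an estimated correlation). ND4L, a complex I subunit, stood at 592 ± 5.08 CPM in DMSO and 298 ± 120 CPM with the activator (SD, n = 2 each). The ribosomal RNA mt-Rnr1 fell from 367 ± 6.80 to 193 ± 79.5 CPM. The other, mt-Rnr2, stood at 66082 and 62323 CPM in DMSO and 34313 and 38024 CPM with the activator. It did not pass the test (-0.83 ± 0.36 SE, limma adjusted p = 0.0662). The libraries were depleted of ribosomal RNA, and how far depletion set the levels of both was not tested. Other fits called mt-Rnr2 lower, among them limma's robust model (adjusted p = 7.54e-12), limma without the variance trend (0.00863), with the replicate block (0.00855) or at a pseudocount of 0.1 (0.0248), edgeR with TMM (0.00109) and DESeq2 (3.56e-19). It was not called with size factors (0.330) or without p53 activator replicate 1 (0.711) or 2 (0.623). Quantile normalization says nothing of mt-Rnr2, since it gives the gene that ranks highest in every library the same value. The calls of ND4L and mt-Rnr1 ended under limma's robust variance model, and without p53 activator replicate 1, 6 protein genes fell. Quantile normalization left 8 lower and 1 higher.

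Of the cell type lists, those of excitatory and inhibitory neurons were called higher at the preset correlation, with an adjusted p = 0.796 and 0.593 with an estimated correlation. The oligodendrocyte lineage and microglia lists were not called, with medians of 0.16 and 0.12, and the lists were not tested against each other. Of 12 excitatory neuron markers 4 rose and 0 fell (median 0.14, camera adjusted p = 0.0370; adjusted over the list alone 4 and 0), among them the vesicular glutamate transporter Slc17a7, from 260 ± 25.5 to 351 ± 21.6 CPM, and the transcription factor Neurod6, from 108 ± 1.17 to 138 ± 4.80 CPM. Of 13 inhibitory neuron markers 6 rose and 0 fell (median 0.20, adjusted p = 0.0302; adjusted over the list alone 6 and 0), among them Slc32a1 (0.58) and Reln, which encodes the secreted protein reelin, from 182 ± 20.1 to 268 ± 29.8 CPM. Among protein-coding genes the 2 lists had an adjusted p = 0.279 and 0.0770. Their medians, 0.14 and 0.20, stood beside 0.16 and 0.10 for protein-coding lists matched on expression (adjusted p = 0.832 and 0.288 against these). The excitatory list lost its call without DMSO replicate 1 (adjusted p = 0.170) or p53 activator replicate 2 (0.201), and the inhibitory list without p53 activator replicate 1 (0.0527). Of 14 astrocyte markers the glutamate transporter Slc1a2 rose (1310 ± 1.24 to 1571 ± 1.93 CPM), and the list was not called (adjusted p = 0.459). The call of Slc1a2 was lost in edgeR with TMM (adjusted p = 0.108). None of 8 oligodendrocyte lineage, 4 microglia, 8 fibroblast or 12 progenitor markers was called by limma (list adjusted p = 0.354, 0.955, 0.892 and 0.852). The most abundant member of the oligodendrocyte lineage, fibroblast and progenitor lists stood at 108 ± 4.95 and 122 ± 4.46 CPM for Olig1, 73.7 ± 0.321 and 81.8 ± 2.21 CPM for Vim and 212 ± 18.8 and 206 ± 21.3 CPM for Fabp7, in DMSO and activator libraries. Of 5 endothelial markers Kdr rose, at 0.472 ± 0.183 and 1.17 ± 0.0992 CPM, and its call was lost without any 1 of the 4 libraries and in edgeR with TMM (adjusted p = 0.0530; list adjusted p = 0.905). Of the 15 microglia and 13 endothelial markers chosen, 5 and 5 were listed in the table. With protein-coding genes scaled to their own total, 4 progenitor markers and 1 microglia marker fell.

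Most classes of noncoding RNA had more falls than rises. Of 1095 long noncoding RNAs (lncRNAs), 452 fell and 15 rose, with a median log2 fold change of -0.37 (quartiles -0.64 and -0.13). Of 504 antisense lncRNAs 266 fell and 3 rose (median -0.50), of 308 intergenic lncRNAs 99 fell and 7 rose (median -0.27), and of 14 sense intronic lncRNAs 10 fell and 0 rose (median -0.63). Among small RNAs, 24 of 38 small nuclear RNAs fell (median -0.54) and 21 of 46 small nucleolar RNAs fell (median -0.44), with 0 higher in either class. Together with the small Cajal body RNAs, 49 of 90 fell, and 31, 26, 27 and 38 without DMSO replicate 1, DMSO replicate 2, p53 activator replicate 1 and p53 activator replicate 2, 19 under quantile normalization, 27 without limma's variance trend and 12 in DESeq2. Of 2365 genes with no single GENCODE match 52.2% fell and 2.49% rose (median -0.50), and of 21 microRNAs 9 fell and 1 rose (median -0.34). By contrast, 3 of 33 bidirectional promoter lncRNAs fell and 0 rose (median -0.09), 22 of 188 processed pseudogenes rose and 25 fell (median -0.04), and 4 of 37 transcribed processed pseudogenes rose and 5 fell (median 0.01). Nuclear protein-coding genes had a median of 0.09, with 2708 higher and 917 lower among 12762. The counting is not stated to use strand, so the values of antisense RNAs are uncertain and may include reads of their partners. The lncRNA median was -0.16 under quantile normalization, where 258 fell, and -0.57 with edgeR's TMM, 247 fell in DESeq2, and 251 lncRNAs fell without DMSO replicate 1 and 297 without p53 activator replicate 2. Scaling protein-coding genes to their own total moved their median by 0.14, from 0.09 to -0.04, so that their rises above are relative to that choice.

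**Figure D4:**
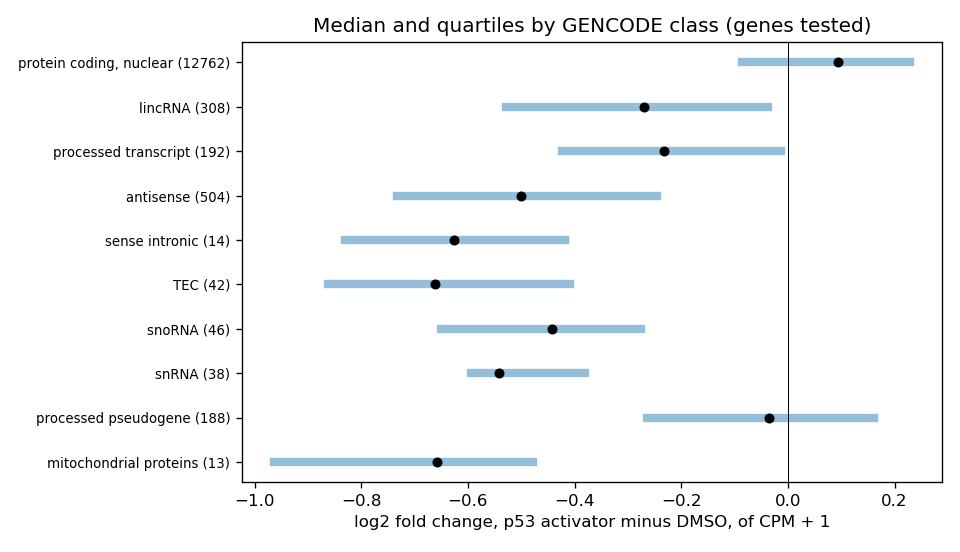
Log2 fold change of CPM + 1, p53 activator minus DMSO (horizontal axis), by GENCODE class, with the number of genes tested in brackets. Dots are medians and bars run from the lower to the upper quartile across genes, and the median is 0.09 for nuclear protein-coding genes and -0.50 for antisense lncRNAs.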

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

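Tests on the recovered reads and on protein-coding genes alone were chosen after seeing the data. The main test gave 2811 genes higher and 2721 lower, 2708 and 917 of them nuclear protein-coding genes. It gave 10 p53 targets higher and 0 lower, and 14 called lists. The count of higher genes was 1632 with quantile normalization, 302 without the variance trend, 1872 with edgeR's TMM, 1745 with edgeR and no filter, and 3 (against 262 lower) at an absolute log2 fold change of at least 1. A minimum of 5 CPM gave 1776 lower genes and 9 called lists. DESeq2 gave 1307 higher, 1508 lower and 3 p53 targets higher. Protein-coding genes scaled to their own total gave 554 higher, 1665 lower, 0 p53 targets higher, 1 lower, Mdm2 at -0.31 and 6 called lists, 5 of them among the 14. Cyclic loess gave 636 higher, 1243 lower, 0 p53 targets higher, 1 lower, Mdm2 at -0.29 and 5 called lists, 3 of them among the 14. Quantile normalization called Mdm2 lower (-0.24), the 1 p53 target lower there, and 0 targets rose without the variance trend. The cause was not tested, except that the fold limit and the stricter minimum leave fewer genes.

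The camera adjusted p of the p53 targets was 0.0480 in the main test. It was 0.189 at 5 CPM, 0.244 among protein-coding genes, 0.115 after loess, 0.0553 with ranks by the moderated t and 0.796 with an estimated correlation, under which 0 lists were called. After loess the excitatory synapse list turned lower (adjusted p = 0.0305), as did the ion channel list, which was not called (0.607). Leaving out 1 library gave 1138 to 2122 genes higher, 1445 to 2468 lower, 3 to 9 p53 targets higher, 0 to 1 lower and a camera adjusted p of 0.0261 to 0.145; the arm left with 1 library was assumed to vary like the other.

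The replicate numbers are shared by the groups but nothing says that they pair the samples. The deviations of the replicate 1 libraries from their group means had a correlation of 0.117 across genes. With 2 libraries per group the replicate 2 deviations only mirror these, so the value does not settle the pairing. With the replicate number as a block 3705 genes were higher and 3132 lower, and the p53 target list had a camera adjusted p of 0.0741. Of the results on single named genes, 1363 values under alternatives kept their side of the threshold, 178 lost the call and 5 gained one. Keeping the highest of rows that share a symbol was not run, since no symbol occurs more than once. Depth limits low genes most: 1 CPM is 14.6 to 19.1 reads.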

Other observations

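Of the tests below, those on unspliced transcripts, on mitochondrial reads, on the p53 targets and on Bc1 were chosen after the result was seen, and those on detained introns and on genomic DNA before.

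Several RNAs known to stay in the nucleus fell, and the genes in this paragraph were picked after their values were seen. Meg3, an imprinted lncRNA, stood at 1833 and 1575 CPM in DMSO and 978 and 829 CPM with the activator (log2 fold change -0.92 ± 0.10 SE, limma adjusted p = 7.73e-13). Kcnq1ot1, which silences neighbouring imprinted genes, stood at 830 and 756 CPM against 416 and 358 CPM (-1.03 ± 0.09). Miat (-0.83), Snhg14 (-0.73) and Neat1, the scaffold of paraspeckles (-0.61), fell too, and all 5 also fell under quantile normalization and in edgeR's test with TMM. Malat1, the most abundant of these lncRNAs, stood at 11283 and 9217 CPM against 7343 and 6426 CPM (-0.57, adjusted p = 0.00942), but lost its call with size factors (adjusted p = 0.0914) and without p53 activator replicate 1 (0.245) or 2 (0.435). Xist fell by 0.40 on the log2 scale and lost its call without p53 activator replicate 2 (adjusted p = 0.0555). Rian, another imprinted lncRNA, did not pass the test (0.00 ± 0.09, adjusted p = 0.993), but was called lower under quantile normalization (-0.20). Gm26917, an intergenic lncRNA by its GENCODE class, rose from 2199 and 2081 CPM to 3078 and 3303 CPM (0.58 ± 0.12, limma adjusted p = 7.82e-05). Its log2 fold change was 0.52 without p53 activator replicate 2. Whether its reads came from a lncRNA held in the nucleus was not tested. Among mRNAs, Leng8 (-0.75), Cwc22 (-0.56), Snrnp70 (-0.54), Nktr (-0.50), Pnisr (-0.49) and Luc7l2 (-0.48) fell, while other genes of splicing, such as Son (0.05), Srrm2 (-0.03) and Srsf2 (-0.01), were not called. Of small RNAs made by RNA polymerase III, Rn7sk (-0.58) and Rmrp (-0.61) fell and Rpph1 did not pass the test (0.15, adjusted p = 0.211), but was called higher without DMSO replicate 1 (0.29, adjusted p = 0.0226) and stood near 0 without DMSO replicate 2 (0.004) or p53 activator replicate 2 (0.005). The calls of Rn7sk and Rmrp ended under limma's robust model (adjusted p = 0.226 and 0.394), without its variance trend (0.108 and 0.115), in DESeq2 (0.295 and 0.332) and without p53 activator replicate 1 (0.0767 and 0.0502), where their log2 fold changes were -0.30 and -0.26.

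The fall of noncoding RNAs beside the rise of abundant mRNAs may reflect fewer unspliced or nuclear transcripts in the p53 activator libraries. That would not account for the fall of mitochondrially encoded RNAs or of Bc1, an RNA of dendrites. LncRNAs within introns of protein-coding genes on the same strand had a median log2 fold change of -0.86 (25 genes), against -0.27 for 128 lncRNAs outside such genes. The difference was -0.58 (permutation p = 1e-04, two-sided, the smallest that 10000 permutations across genes can give). That p measures the spread between genes of the same 4 libraries and not between samples, and the sets were not matched on expression. The 65 lncRNAs in introns on the opposite strand had a median of -0.92, which unstranded counting of the host would also give. A list of 26 genes known for introns detained in the nucleus, written after Leng8, Nktr and Pnisr were seen to fall but without them and before its own values were seen, had a median of -0.22 where matched protein-coding lists gave 0.17 (95% of them from 0.08 to 0.24), with 16 lower and 0 higher (3 lower without DMSO replicate 1, 9 without p53 activator replicate 2, and 1 lower without limma's variance trend). Genomic DNA in the DMSO libraries is argued against as the whole cause. The excess of CPM per exonic kb was 172 times as large in intronic lncRNAs as in the least expressed 10% of protein-coding genes. These sets were picked at unlike levels of expression, so a part played by DNA stays open. Fewer mitochondrial reads would account for part of the mRNA rise and, by construction, for none of the lncRNA fall. With those reads left out of the totals the median of protein-coding genes went from 0.09 to 0.011. That of the 12.5% most expressed went from 0.21 to 0.12 (0.08 to 0.14 over the 4 pairs of a DMSO and an activator library). An effect of Nutlin-3 on transcription or splicing and a difference between groups in RNA extraction or library preparation stay open, as untested, because each would follow the groups.

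Of the 47 p53 targets 10 rose, by small margins. That is 21.3%, beside 21.2% of all nuclear protein-coding genes, and these shares were neither matched on expression nor tested against each other. Mdm2 and Cdkn1a were not called, nor was Trp53, whose mRNA does not check the drug. A library scaling that hides a rise of 1.5-fold or more in most of the targets is argued against. The targets' median lay 0.080 above that of matched protein-coding lists, higher than 97.9% of them. With the spread of those random lists, which is not an interval for the targets, that difference reaches 0.16. A 1.5-fold rise would show a median of 0.54 on the log2(CPM + 1) scale. A rise in a minority of the targets would move the median little, so it stays open. The bound of 1.5-fold was set after the difference of 0.080 was seen, so its outcome was known. It took the place of an earlier bound, the top 2.5% of matched lists. The targets reach that earlier bound, and under it a smaller hidden rise stays open. For 46 of 47 targets the upper 95% limit was below what a 2-fold rise of their own DMSO level would show on the log2(CPM + 1) scale. For these a lack of precision for a 2-fold rise is argued against, but only for the spread between these libraries. That spread is shared across genes by limma, and variation between cultures may be missing from it, since the libraries of a group may not be separate cultures. For Perp a lack of precision stays open. The activity of the compound, its dose and a response that had ended by 2 days were not tested.

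Bc1 may have fallen through a change in its transcription or through the way short RNAs were captured. Other nuclear-encoded RNAs under 400 bases had a median log2 fold change of -0.37 (74 genes, quartiles -0.58 and -0.02, lowest -1.09). A general loss of short nuclear-encoded transcripts thus falls well short of the -3.21 of Bc1, which is 168 bases long. That set left out mitochondrial RNAs, of which ATP8 (-1.63), TrnE (-1.26) and TrnS1 (-1.25) fell further than its lowest member. The small RNAs Rn7sk, Rmrp and Rpph1 shared the order of Bc1 within groups. They were higher in DMSO replicate 1 than 2 and lower in p53 activator replicate 1 than 2. A difference between libraries in the capture of short RNAs therefore stays open. No single library made the fall: it was -2.28 at its smallest, without p53 activator replicate 1, and -4.15 at its largest, without p53 activator replicate 2. Within groups Bc1 differed from 123 to 319 CPM and from 10.2 to 40.1 CPM, reads from near-identical repeats of the same family were not separated, and a biological cause was not tested.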
